A study of Arabidopsis thaliana with 15 samples.

How the data were processed

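RNA of whole seedlings, 30 per sample, had been made into stranded mRNA libraries from 400 ng of total RNA and sequenced as 100 bp single-end reads, per the labels. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.3a, HTSeq 0.9.1, edgeR 3.22.3 and the genome build TAIR10, without their roles. The deposited count table gives raw read counts per gene and library, made by the authors and neither scaled nor pooled, and all comparisons were computed from it. The second deposited table holds normalized signal, in which the authors multiplied each count by 1 factor per library (implied scaling 0.891 to 1.14) and left out genes by a filter that is not stated. It was used only as an alternative set of genes, and 59 of its genes have no reads in any library. The strand setting of the counting is not stated, so reads of overlapping genes can be miscounted, and near-identical family members such as the SAUR19 group share reads. No coordinates are given, since the name table follows a later release of the annotation than the authors' build. Gene names came from that table, in which 32835 genes were matched.

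The 15 libraries formed 5 groups of 3 by genotype and light, from the sample titles. They held 19.3 to 30.4 M reads, and a gene with no reads in a library is bounded by 3 reads, which covers counting error alone. Genes were kept by edgeR's filterByExpr on the 5 groups, which left 20833 genes. Scaling was by TMM (factors 0.863 to 1.11). One negative binomial model with a term per group was fitted to all 15 libraries with 10 residual degrees of freedom, and comparisons were tested with edgeR 4.0.16's quasi-likelihood F test in R 4.3.3. P values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Errors of log2 fold changes are standard errors from the fit, and levels are CPM (counts scaled to the TMM library size) with the standard deviation over 3 libraries.

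The comparisons were UV-B against white light in wild type and in uvr8-6, the difference of these responses, uvr8-6 and pif4-101 pif5-1 against wild type in white light, and wild type against uvr8-6 under UV-B. Genes were named by rule: the 8 largest changes per direction among called genes with at least 5 CPM in the higher group and libraries that did not overlap (not asked of the difference of responses), members of the lists, the targeted genes and the genes shared between comparisons. MRD1, HEI10 and the genes of the last part of the text were singled out after their values were seen. The 19 gene lists (353 genes) covered UV-B, flavonoid, phenylpropanoid, DNA damage, PIF target, auxin, cell wall, brassinosteroid, gibberellin, B-box, PIF family, clock, photosynthesis, salicylic acid, jasmonate, heat shock, cell cycle, root and seed genes. They were tested with limma 3.58.1's camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over the lists of a comparison. Limma's fry asked whether a list itself moved, without regard to other genes, and was adjusted alike. Comparisons, lists, the naming rule and most alternatives were fixed before the data were examined. The added alternatives, chosen after seeing the data, were the removal of a pair of wild-type libraries, 1 surrogate variable (sva 3.50.0), the genes of the normalized table, the white-light libraries alone with a replicate block, list tests with libraries left out, and for the DNA damage list in uvr8-6 an estimated correlation joined with left-out libraries or the surrogate variable.

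Alternatives were other scalings, filters and tools (DESeq2 1.42.0 and limma-voom), the replicate number as a block, the compared libraries alone, and each library left out in turn. Deviations from the group mean were correlated between libraries of equal number. Between uvr8-6 and wild type in white light these were 0.33, 0.60 and 0.39, so these libraries may be paired by replicate number. Replicate 2 lay apart in both groups, and deviations within a group depend on each other, so a pairing is not settled. Between both genotypes under UV-B the correlations were 0.26, 0.38 and -0.02. The main fits held no replicate block. With the block edgeR called 3 genes between these genotypes in white light, as without it. The method was tested on simulated counts with 50 changed genes per fold. For the wild-type UV-B response 78% of 2-fold and 34% of 1.5-fold changes were called, and for the difference of the responses 48% and 8%. The simulation changed fewer genes than were called in these comparisons and drew independent libraries, so these shares do not measure what was missed.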

Results

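RNA was sequenced from whole Arabidopsis thaliana seedlings of 3 genotypes, the Col-0 wild type, uvr8-6, which lacks the UV-B photoreceptor UVR8, and pif4-101 pif5-1, which carries lesions in the growth-promoting transcription factors PIF4 and PIF5. Seedlings were 4 days old and either stayed in low white light or received 6 h of supplementary narrowband UV-B. Wild type and uvr8-6 were sampled in both conditions and pif4-101 pif5-1 in white light alone, which gave 15 libraries in 5 groups of 3. Per the series design the replicates came from independent plates. The libraries held 19.3 to 30.4 M counted reads, and 20833 genes had enough reads to be tested. The first principal component took 37.9% of the variance and set the 3 wild-type UV-B libraries apart from the other 12 in the plot of principal components.

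**Figure D1:**
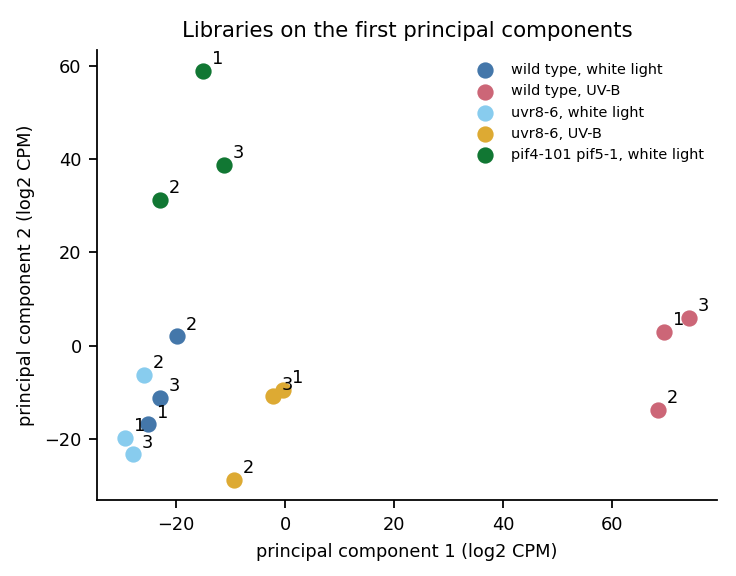
Each point is 1 of the 15 libraries, coloured by group and numbered by replicate, on the first and second principal components of log2 CPM (37.9% and 16.5% of the variance). The wild-type UV-B libraries lie alone at the right, and the pif4-101 pif5-1 libraries lie apart along the vertical axis.

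The targeted genes were examined first. UVR8 (AT5G63860) stood at 99 ± 14.1 CPM, which are read counts scaled to library size (SD, n = 3), in wild type in white light and at 17.0 ± 2.8 in uvr8-6, and at 90.0 ± 7.4 and 15.4 ± 0.5 under UV-B. PIF5 (AT3G59060) stood at 108.3 ± 29.7 CPM in wild type and at 5.0 ± 0.4 in pif4-101 pif5-1 in white light. PIF4 (AT2G43010) stood at 126.6 ± 56.6 CPM in wild type and at 87.4 ± 11.0 in pif4-101 pif5-1, and that difference was not called by edgeR (adjusted p = 0.49). Counts over a whole gene do not check the pif4-101 allele, since reads outside a lesion are counted too. The PIF4 level differed within the wild-type white-light group, with 62.1 CPM in replicate 2 and 149.3 and 168.3 CPM in the others.

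Which genes respond to UV-B was asked first in wild type. Genes of UV-B photomorphogenesis rose together. ELIP1 (AT3G22840), which encodes a photoprotective early light-induced protein, went from 0.303 ± 0.171 to 145.5 ± 22.6 CPM (SD, n = 3), a log2 fold change of 8.90 ± 0.35 (SE). CHS (AT5G13930), the entry enzyme of flavonoid synthesis, went from 26.5 ± 22.6 to 2728 ± 282 CPM. The bZIP transcription factor gene HY5 (AT5G11260) went from 17.5 ± 4.5 to 69.3 ± 3.7 CPM, and RUP2 (AT5G23730), which encodes a repressor of UVR8, from 18.9 ± 7.0 to 172.4 ± 8.0 CPM. The largest decreases among the genes selected by rule included PORA (AT5G54190), a protochlorophyllide oxidoreductase gene, with a log2 fold change of -4.55 ± 0.42, and WAG2 (AT3G14370), a kinase gene of auxin transport, with -3.06 ± 0.25.

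By gene list, 21 of 23 tested members of the UV-B photoreceptor pathway and its markers rose in wild type and none fell (21 adjusted over the list alone), among them RUP1 with a log2 fold change of 1.97 ± 0.11 and GPX7 with 7.81 ± 0.39. Of the 22 tested flavonoid and anthocyanin genes 18 rose (22 adjusted over the list alone), including FLS1 (6.55 ± 0.64), F3H (6.34 ± 0.34) and the regulator MYB12 (4.32 ± 0.19). Of 18 phenylpropanoid and sinapate ester genes 13 rose and 1 fell (14 and 2 adjusted over the list alone), with UGT84A1 at 7.39 ± 0.34 and PAL1 at 2.28 ± 0.14. These 3 lists passed the camera test of a list against all other genes (adjusted p = 1.7e-52, 1.9e-36 and 2.0e-20), and they passed with an estimated correlation (adjusted p = 9.7e-06, 0.00836 and 0.00484). Genes of the B-box proteins rose in 8 of 12 cases and fell in 1 (9 and 1 adjusted over the list alone), with BBX32 at 3.5 ± 0.39 (camera adjusted p = 0.000107, and adjusted p = 0.22 with an estimated correlation). Circadian clock genes rose in 11 of 21 cases and fell in 3 (11 and 3 adjusted over the list alone), with ELF4 at 1.77 ± 0.17 (camera adjusted p = 0.00893, and adjusted p = 0.22 with an estimated correlation). For the B-box and clock lists the fry test gave adjusted p = 0.00025 and 0.00018.

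In wild type under UV-B, of 27 PIF target and shade avoidance genes 19 fell and 1 rose (20 and 1 adjusted over the list alone), of 42 auxin genes 15 fell and 1 rose (16 and 2), and of 25 cell wall loosening genes 13 fell and 2 rose (14 and 2). IAA19, an auxin-responsive repressor gene, had a log2 fold change of -2.46 ± 0.43, GH3.3, an auxin-conjugating enzyme gene, -2.69 ± 0.40, XTH19 -2.03 ± 0.22 and EXPB1 -2.10 ± 0.18. The camera test gave adjusted p = 6.4e-06, 0.00176 and 0.000362 for these lists. With an estimated correlation it gave adjusted p = 0.46, 0.65 and 0.41, so that their camera calls rest on the preset correlation. The fry test, which asks whether a list itself moved, gave adjusted p = 0.027, 0.15 and 0.0091. In gibberellin metabolism 4 of 12 genes rose and 1 fell (4 and 2 adjusted over the list alone), with GA20OX1 at -2.81 ± 0.40 and GA2OX8, a gibberellin-inactivating enzyme gene, at 2.24 ± 0.42. Among 10 brassinosteroid genes 5 fell and 2 rose (6 and 2 adjusted over the list alone), with BR6OX1 at -1.54 ± 0.19. In 7 PIF family genes 3 rose and 1 fell (3 and 2), among them PIF8 at 1.70 ± 0.11 and PIF3 at -0.83 ± 0.17.

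Of the other lists in wild type under UV-B, in photosynthesis and chlorophyll synthesis 8 of 27 genes rose and 2 fell, in heat shock and oxidative stress 6 of 15 rose, in the salicylic acid list 2 of 14 rose and 3 fell, in the jasmonate list 2 of 12 fell, in the DNA damage list 2 of 18 rose and 1 fell, in cell cycle genes 1 of 14 rose and 2 fell, and among root markers 2 of 15 fell. The counts adjusted over each list alone were equal to these. None of these 7 lists passed the camera test (the lowest adjusted p was 0.0715), nor did the brassinosteroid, gibberellin and PIF family lists. By fry, which asks whether a list itself moved, the PIF family (adjusted p = 0.0035), heat shock (0.0079) and brassinosteroid lists (0.012) were called. The others were not (the lowest adjusted p by fry was 0.092, for the DNA damage list). Camera calls near the threshold, all at the preset correlation, turned with 1 library left out. With all libraries and an estimated correlation camera gave adjusted p = 0.76 for the photosynthesis and 0.52 for the heat shock list. For the brassinosteroid and root lists it gave 0.46 and 0.65. The photosynthesis list was called without wild-type white-light replicate 1 (0.0239) or UV-B replicate 1 (0.0403) or 2 (0.0102), and the heat shock list without white-light replicate 1 (0.0383) or UV-B replicate 1 (0.0157) or 3 (0.0367). The brassinosteroid list was called without white-light replicate 2 (0.0311) and the root list without UV-B replicate 1 (0.0351). With upper quartile scaling the heat shock list was called at 0.0392 and with 1 surrogate variable at 0.0228, and with the replicate block the photosynthesis (0.0412) and brassinosteroid lists (0.0467). In the gibberellin list the median and the mean differed in sign (-0.19 and 0.35). Of the 10 tested seed storage and late embryogenesis genes edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 calls from DESeq2 or limma-voom.

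In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5700 genes in wild type, of which 3354 rose and 2346 fell. Changes of at least 2-fold were found in 1106 of the genes that rose and 675 of those that fell. The share that rose was 58.8% and depended on the scaling. With upper quartile scaling, which moved the median log2 fold change of all genes to -0.11, 40.7% of 6511 called genes rose.

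Whether the response needs UVR8 was asked in uvr8-6 and by the difference of the responses. In uvr8-6 edgeR called none of the UV-B pathway genes. CHS stood at 26.0 ± 13.8 CPM in white light and 65.3 ± 26.2 under UV-B (SD, n = 3), HY5 at 18.3 ± 0.9 and 19.3 ± 2.6, RUP2 at 14.4 ± 2.7 and 20.4 ± 2.2 and ELIP1 at 0.567 ± 0.297 and 1.26 ± 0.41, and DESeq2 called ELIP1 (adjusted p = 0.0403). Over the UV-B pathway list edgeR called 0 of 23 genes in uvr8-6 (0 adjusted over the list alone), with 11 at an unadjusted p under 0.05, 1 call from DESeq2 and 0 from limma-voom. The flavonoid list had 0 of 22 calls (5 rose adjusted over the list alone), with 7 at an unadjusted p under 0.05, 2 calls from DESeq2 and 1 from limma-voom. Both lists lay higher than other genes in the camera test (adjusted p = 9.6e-05 and 1.9e-06, and adjusted p = 0.13 and 0.32 with an estimated correlation).

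**Figure D2:**
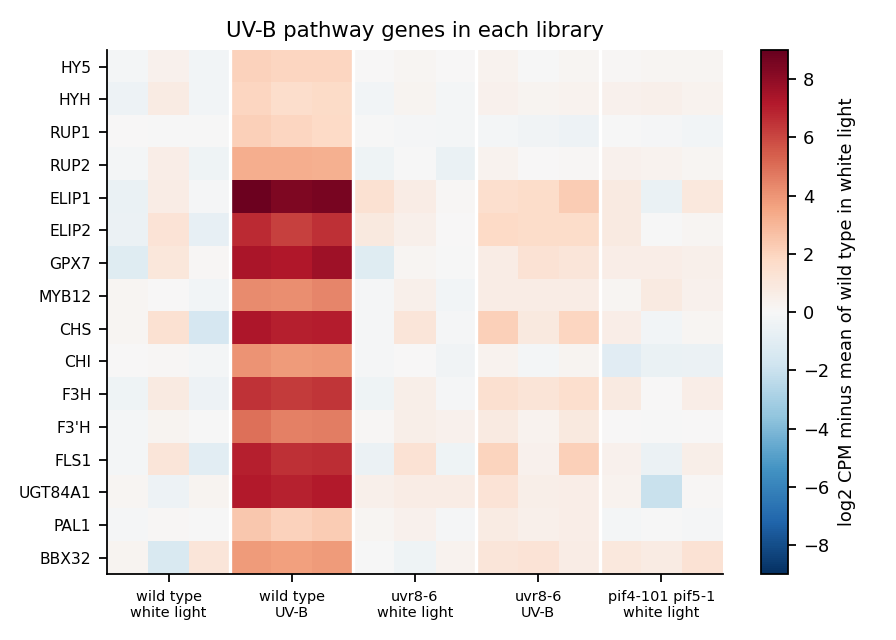
Rows are 16 chosen genes of the UV-B pathway and of flavonoid and phenylpropanoid synthesis, with BBX32 from the B-box list. Columns are the 15 libraries by group, and colour gives log2 CPM minus the mean of the wild-type white-light libraries. The 3 wild-type UV-B libraries are higher for each of these chosen genes, while not all members of their lists rose. CHS stood at 2728 CPM on average there and at 65.3 CPM in uvr8-6 under UV-B.

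Outside these lists edgeR called other genes in uvr8-6. ABCG6 (AT5G13580), a transporter gene of suberin export, rose with a log2 fold change of 2.51 ± 0.32, and CYP86B1, an enzyme gene of very long chain suberin monomers, with 2.19 ± 0.31. PELPK1 (2.24 ± 0.29), PELPK2 (2.61 ± 0.35) and CYP72A8 (2.33 ± 0.29) rose too, and CYP71A16 fell by 1.25 on the log2 scale. Among 18 DNA damage response genes 3 rose (8 adjusted over the list alone), led by the repair gene BRCA1 with 1.59 ± 0.22, and the list passed the camera test with the preset and the estimated correlation (adjusted p = 1.7e-10 and 0.0219). With the estimated correlation that call ended without white-light replicate 2 (0.0698) or UV-B replicate 2 (0.0572) of uvr8-6 and with 1 surrogate variable (0.0661), and over single left-out libraries 1 to 4 of the genes rose. Of 15 heat shock and oxidative stress genes 3 rose (3 adjusted over the list alone), the camera test gave adjusted p = 0.000517, and adjusted p = 0.32 with an estimated correlation. Without white-light replicate 2 or UV-B replicate 2 of uvr8-6 the adjusted p of that list was 0.123 and 0.155. Its 3 genes, GSTU24, GSTU25 and AOX1A, all lost their call without white-light replicate 1 (0.057, 0.0603 and 0.0604) or 3 (0.051, 0.0813 and 0.0764) of uvr8-6, which left 0 called. The auxin and cell wall loosening lists lay lower under UV-B (camera adjusted p = 6.7e-05 and 0.000293, and adjusted p = 0.56 and 0.34 with an estimated correlation). EdgeR called 0 of 42 and 0 of 25 of their genes, with 8 and 5 at an unadjusted p under 0.05 and 0 calls from DESeq2 or limma-voom. The PIF target (0.00154) and brassinosteroid lists (0.00986) lay lower and the phenylpropanoid list (0.00121) higher, with adjusted p = 0.64, 0.32 and 0.32 with an estimated correlation. The PIF target call ended without white-light replicate 1 of uvr8-6 (0.15). Their calls of single genes were 1 of 27 that rose, 1 of 10 that fell and, by edgeR, 0 of 18, with 7 at an unadjusted p under 0.05, 1 from DESeq2 and 0 from limma-voom. The seed storage list lay higher (0.00962, and adjusted p = 0.38 with an estimated correlation), with 0 of 10 genes called by edgeR, 4 at an unadjusted p under 0.05 and 0 from DESeq2 or limma-voom. That call ended without UV-B replicate 2 of uvr8-6 (0.303), in which CRU3 stood at 17.9 and CRA1 at 31.1 CPM.

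Some libraries differed within their groups, and a set of 5 was formed from the data by its FRO5 level. This reductase gene was high in white-light replicate 2 and UV-B replicates 1 and 3 of uvr8-6, and in white-light replicate 2 and UV-B replicate 1 of wild type. Among the 25 genes with the lowest p between these libraries and the others of their groups were PIF4, with a difference of -1.12 on the log2 scale, ATHB2 (-1.75), PRE1 (-0.88) and HAT2 (-0.84), singled out after their values were seen. The gene lists were not tested on this set. IAA19 stood at 82.7, 28.5 and 70.2 CPM in uvr8-6 in white light and at 29.8, 44.5 and 31.8 CPM under UV-B. In wild type in white light it stood at 64.1, 21.8 and 49.9 CPM.

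EdgeR called 233 genes in uvr8-6, of which 177 rose and 56 fell (2720 at an unadjusted p under 0.05), and 108 changed at least 2-fold. Of these, 179 were called in wild type in the same direction, 2 in the opposite direction and 52 were not called there. The count depended on single libraries and on the method. It was 43 without white-light replicate 1, 49 without white-light replicate 3, 120 without UV-B replicate 1, 100 without UV-B replicate 3 and 393 without UV-B replicate 2 of uvr8-6, 629 with DESeq2 and 386 with 1 surrogate variable in the fit. When the 6 uvr8-6 libraries were fitted alone the real grouping called 167 genes, and another grouping, which set white-light replicates 1 and 3 and UV-B replicate 2 against the rest, called 568.

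The difference of the UV-B responses was tested directly. The response of ELIP1 was larger in wild type than in uvr8-6 by 7.73 ± 0.66 on the log2 scale (SE), that of UGT84A1 by 7.14 ± 0.61, that of CHS by 5.37 ± 0.79 and that of HY5 by 1.92 ± 0.20. The responses of PORA (-3.60 ± 0.53), WAG2 (-3.12 ± 0.33), ADS4 (-3.24 ± 0.29) and GH3.3 (-3.18 ± 0.53) were lower in wild type. CHX17, a cation exchanger gene, had a difference of -2.36 ± 0.51 and stood at 35.2 ± 4.9 CPM in uvr8-6 under UV-B, against 9.66 ± 2.59 in white light.

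The difference was positive for 20 of 23 UV-B pathway genes (21 adjusted over the list alone), for 14 of 22 flavonoid genes (14) and for 8 of 18 phenylpropanoid genes, with 1 negative (9 and 2). These lists passed the camera test with the preset correlation (adjusted p = 1.2e-51, 3.2e-42 and 5.0e-19) and with the estimated one (adjusted p = 1.6e-05, 0.00523 and 0.00523). B-box genes had a positive difference in 5 of 12 cases (8 and 1 adjusted over the list alone), with BBX22 at 1.27 ± 0.22 and BBX25 at 0.92 ± 0.14 (camera adjusted p = 1.2e-05, and adjusted p = 0.14 with an estimated correlation). Clock genes had 3 positive and 1 negative difference among 21 (8 and 2 adjusted over the list alone), with ELF4 at 1.59 ± 0.24 (camera adjusted p = 0.000509, and adjusted p = 0.082 with an estimated correlation). PIF target genes had 2 negative differences among 27 (2 adjusted over the list alone, camera adjusted p = 0.000192, and adjusted p = 0.48 with an estimated correlation). Auxin genes had 1 positive and 3 negative differences among 42 (2 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0994, and adjusted p = 0.79 with an estimated correlation). By fry the B-box and clock lists gave adjusted p = 0.0060 and 0.0014, and the PIF target and auxin lists 0.28 and 0.69.

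Of the 1106 genes that rose at least 2-fold in wild type, 599 (54.2%) had a called difference, and their median log2 fold change was 1.45 in wild type and 0.38 in uvr8-6. Of the 675 that fell at least 2-fold 184 (27.3%) had a called difference, with medians of -1.48 and -0.41. These genes were chosen by their wild-type change, which fixes the wild-type medians beyond 2-fold, so the medians are not on equal terms. The choice also favours a called difference, since both use the same wild-type libraries. In uvr8-6 978 (88.4%) of the first set and 577 (85.5%) of the second went in the wild-type direction. EdgeR called 1375 genes for the difference, 1016 positive and 359 negative, and 664 with at least a 2-fold difference. The share positive was 73.9%, and 56.1% with upper quartile scaling. The count was 877 without white-light replicate 3 of uvr8-6, 1759 with the replicate block and 2156 with 1 surrogate variable. That variable was drawn from the same counts, which can raise the number. Genes called in wild type and in the difference with the same sign, named UVR8-dependent here, numbered 1323, of which 998 rose and 325 fell. Without white-light replicate 3 of uvr8-6 they numbered 855, and with 1 surrogate variable 2061.

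**Figure D3:**
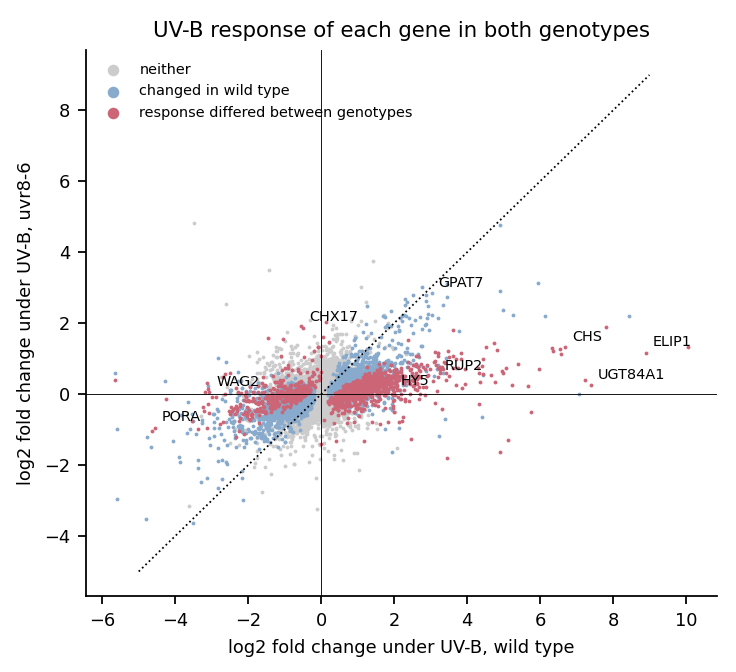
Each point is 1 of 20833 genes, with its log2 fold change under UV-B in wild type on the horizontal axis and in uvr8-6 on the vertical axis. Points in red had a called difference of the responses (1375 genes), and the dotted line marks equal responses.

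How far UVR8 changes expression under UV-B was asked by comparing wild type and uvr8-6 in that condition. ELIP1 was higher in wild type by 6.84 on the log2 scale, CHS by 5.39 and UGT84A1 by 6.49, and PORA (-3.93) and WAG2 (-3.33) were lower. The UV-B pathway list was higher in 21 of 23 cases (22 adjusted over the list alone, camera adjusted p = 1.1e-57, and 1.2e-05 with an estimated correlation). EdgeR called 4903 genes, 2991 higher and 1912 lower in wild type, with 1330 of at least 2-fold. The share higher was 61%, and 42.1% with upper quartile scaling, which moved the median of all genes to -0.10. DNA damage response genes were lower in wild type in 8 of 18 cases and higher in 1 (9 and 1 adjusted over the list alone), with BRCA1 at -0.90 ± 0.21 and GMI1 at -0.73 ± 0.16 (camera adjusted p = 0.00188, and adjusted p = 0.16 with an estimated correlation). Cell cycle genes were lower in 8 of 14 cases and higher in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00642, and adjusted p = 0.47 with an estimated correlation).

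In white light uvr8-6 was close to wild type by calls of single genes. EdgeR called 3 genes, all lower in uvr8-6, which were UVR8, MRD1 (AT1G53480) with a log2 fold change of -6.83 ± 0.40, and HEI10 (AT1G53490), a meiotic crossover gene, with -3.01 ± 0.18. At an unadjusted p under 0.05 there were 415 of 20833 genes, a share below the 0.05 that unchanged genes alone would give. This fit leaves out the possible pairing by replicate number. With the replicate block in the white-light libraries alone there were 684, and 3 genes were called. DESeq2 called 6. None of the 19 lists had a member called by edgeR, DESeq2 or limma-voom. The UVR8 log2 fold change was -2.54 ± 0.13. The photosynthesis list lay lower in uvr8-6 in the camera test (adjusted p = 4.2e-07, and adjusted p = 0.61 with an estimated correlation), with 0 of 27 genes called by edgeR, 0 at an unadjusted p under 0.05 and 0 from DESeq2 or limma-voom. The cell cycle, root and cell wall lists lay higher (adjusted p = 0.00424, 0.0137 and 0.0212, and adjusted p = 0.61 for each with an estimated correlation). The cell cycle call ended without uvr8-6 replicate 2 (0.0589), and the root call without wild-type replicate 1 (0.168) or uvr8-6 replicate 2 (0.369). The cell wall call ended without wild-type replicate 2 (0.508) or 3 (0.0577) or uvr8-6 replicate 1 (0.427) or 3 (0.0984). The PIF target and auxin lists were not called (camera adjusted p = 0.348 and 0.329, and 0.85 for each with an estimated correlation). They lay higher without uvr8-6 replicate 2 (6.9e-08 for each) or wild-type replicate 1 (0.000103 for each). Without wild-type replicate 2 they lay lower (0.00214 and 0.015). MRD1 had 14, 2 and 1 reads in uvr8-6 in white light and 548 to 657 in wild type. Under UV-B it had 0 to 2 reads per library in uvr8-6, for which no fold is given.

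Which genes depend on PIF4 and PIF5 was asked in white light. In pif4-101 pif5-1 PIL1, a shade avoidance transcription factor gene, had a log2 fold change of -4.25 ± 0.58 (SE), IAA29 of -3.87 ± 0.60, IAA19 of -3.22 ± 0.44 and BEE1, a brassinosteroid-responsive transcription factor gene, of -2.08 ± 0.31. The IAA19 level was 45.3 ± 21.5 CPM in wild type and 4.86 ± 0.60 in the mutant (SD, n = 3). Higher in the mutant were BCB, a blue copper protein gene, with 1.91 ± 0.35, the cytokinin response factor gene CRF2 with 1.3 ± 0.19, the GATA factor gene CGA1 with 1.22 ± 0.22 and HEME1, an enzyme gene of tetrapyrrole synthesis, with 1.16 ± 0.21.

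Of 42 auxin genes 27 fell and none rose (35 adjusted over the list alone), of 27 PIF target genes 14 fell (22), of 25 cell wall loosening genes 7 fell (11, with 1 that rose), of 10 brassinosteroid genes 4 fell (5), including BR6OX1 at -1.16 ± 0.19 and DWF4 at -0.76 ± 0.10, and of 12 gibberellin genes 3 fell (4), including GA20OX1 at -2.33 ± 0.38. The camera test gave adjusted p = 2.1e-34, 4.4e-22, 1.2e-06, 3.9e-06 and 0.00316 for these 5 lists. With an estimated correlation it gave adjusted p = 0.073, 0.088, 0.14, 0.073 and 0.14, so that none held with it. The fry test of each list itself gave adjusted p = 0.00685, 0.0135, 0.0213, 0.00184 and 0.0135. Of 7 PIF family genes 2 fell (2, with 1 that rose, adjusted over the list alone), which were PIF5 at -4.43 ± 0.22 and PIF8 at -0.58 ± 0.11. This list holds both mutated genes, so its test is not given. Photosynthesis and clock lists lay higher in the mutant (camera adjusted p = 1.5e-10 and 0.000788, and adjusted p = 0.30 and 0.088 with an estimated correlation), with 1 of 27 and 0 of 21 genes called by edgeR, 15 and 6 at an unadjusted p under 0.05, 9 and 2 calls from DESeq2 and 1 and 0 from limma-voom. SAUR22 (-3.23 ± 0.58) belongs to a family of near-identical copies, and its value is uncertain.

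EdgeR called 1095 genes in pif4-101 pif5-1, 358 higher and 737 lower, and 330 with at least a 2-fold difference. The count was 335 without wild-type white-light replicate 1, 492 without wild-type white-light replicate 3, 381 without replicate 1 and 412 without replicate 3 of pif4-101 pif5-1. It was 278 when these 6 libraries were fitted alone, 1772 with DESeq2 and 1842 with 1 surrogate variable. Wild-type white-light replicate 1 stood out by organelle reads, with 0.4462% mitochondrial and 0.2077% chloroplast reads. The next highest library, uvr8-6 UV-B replicate 3, had 0.1315% and 0.0505%. That wild-type library also held 2341 reads of AT1G15405, against at most 57 elsewhere. With organelle genes removed the count was 1106. Whether this make-up bears on the counts without that library was not tested.

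**Figure D4:**
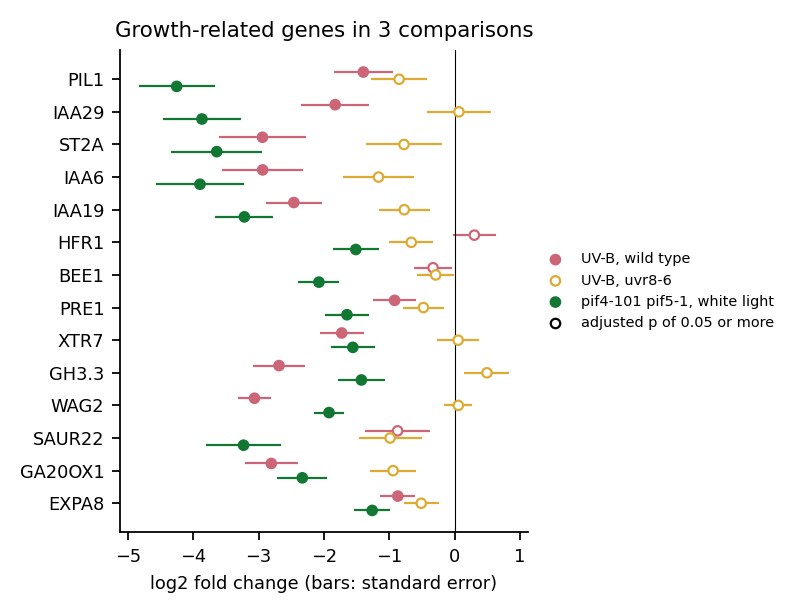
Points give the log2 fold change of 14 growth-related genes under UV-B in wild type, under UV-B in uvr8-6 and in pif4-101 pif5-1 against wild type in white light, with bars for the standard error. Filled points passed an adjusted p of 0.05, which none of the 14 did in uvr8-6.

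The series sets the UVR8-mediated changes beside the genes misexpressed in pif4-101 pif5-1, and the calls of both were crossed. Of the 325 UVR8-dependent genes that fell under UV-B 73 were also lower in pif4-101 pif5-1, where lists drawn independently would share 11.5 (Fisher's exact test, adjusted p = 2.5e-37). WAG2 was among them, with -3.06 ± 0.25 under UV-B and -1.92 ± 0.23 in the mutant, and so was the arabinogalactan protein gene AGP4, with -2.68 ± 0.17 and -0.91 ± 0.16. Of the 998 that rose 56 were also higher in pif4-101 pif5-1, against 17.1 (Fisher's exact test, adjusted p = 8.7e-15), including BCB with 2.72 ± 0.36 and 1.91 ± 0.35 and CGA1 with 1.78 ± 0.22 and 1.22 ± 0.22. Opposite directions were shared by 26 genes that rose under UV-B and were lower in the mutant, PIF8 among them, against 35.3 (Fisher's exact test, adjusted p = 0.13), and by 3 genes that fell and were higher, against 5.6 (adjusted p = 0.41). Fisher's test takes genes as independent, which they are not.

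Both comparisons used the wild-type white-light libraries, which by itself ties their fold changes together. How many of the shared genes this gives was not measured. The covariance of the difference of the responses with the pif4-101 pif5-1 fold changes across genes was 0.0577, against 0.0331 with unchanged groups simulated against the same controls, which leaves 0.0246. The correlation was 0.205 against 0.359 simulated, and these cannot be compared. The simulated fold changes held no effect of UV-B or genotype, so the shared controls made up a larger part of their variance. In comparisons with no library in common, of the genes lower in wild type than in uvr8-6 under UV-B, 256 were lower in pif4-101 pif5-1 than in wild type in white light, against 67.6, and 143 were higher in both, against 51.4. For wild type under UV-B and pif4-101 pif5-1 against uvr8-6 in white light, 478 fell in both, against 150.1. Across the genes of these pairs the covariance was 0.0397 and 0.0764, against -0.0001 and 0.0002 simulated, but the simulated libraries were independent. Wild-type and uvr8-6 white-light libraries of equal number deviated together, so the second pair is not free of shared deviations. Those of pif4-101 pif5-1 and uvr8-6 in white light correlated by 0.16, 0.19 and 0.14, a hint of pairing only, and their comparison had no replicate block. On log2 CPM, where the covariances were 0.0384 and 0.0680, libraries of equal number gave -0.0047 and 0.0166, in a check chosen after the values were seen. Libraries with high FRO5 were not spread evenly either, with 2 of 3 in uvr8-6 under UV-B, 1 of 3 in each other group of wild type and uvr8-6 and 0 in pif4-101 pif5-1, and their part was not measured.

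The number of shared genes depended on single libraries. Of the UVR8-dependent genes, those that fell in both numbered 32 without wild-type white-light replicate 1, 43 without its replicate 3, 43 without replicate 3 of pif4-101 pif5-1 and 124 without wild-type white-light replicate 2. Those that rose in both numbered 7 and 16 without wild-type white-light replicates 1 and 3, 35 and 33 without wild-type UV-B replicates 1 and 3, and 34 and 29 without uvr8-6 white-light replicates 1 and 3. They numbered 36 without uvr8-6 UV-B replicate 3, and 21, 97 and 10 without replicates 1, 2 and 3 of pif4-101 pif5-1. Of the pairs with no shared library, the 256 genes became 110 and 143 without wild-type white-light replicates 1 and 3, 162 without wild-type UV-B replicate 3, and 139 and 119 without replicates 1 and 3 of pif4-101 pif5-1. The 143 genes became 28 and 47 without wild-type white-light replicates 1 and 3, 92 without wild-type UV-B replicate 3, and 39, 238 and 26 without replicates 1, 2 and 3 of pif4-101 pif5-1. The 478 genes became 308 and 281 without uvr8-6 white-light replicates 1 and 3, and 309 without replicate 3 of pif4-101 pif5-1. With DESeq2 130 UVR8-dependent genes fell in both and 118 rose in both.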

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

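The tests of difference between genotypes were planned, the splits were written before their result was seen, and the tests on the DNA damage list were chosen after the result was seen. Groups of 3 libraries were too small for a test of single deviating libraries. The 1375 genes of the difference of the UV-B responses stood out because the effect of UV-B differed between wild type and uvr8-6. The splits do not decide whether chance can be excluded, since the design fixes how many genes they can reach. With the genotypes exchanged within each light condition, the scheme planned first, 8 of 100 splits gave as many genes (real 1590 in these libraries alone, highest other 3903), and 4 of 100 gave as many UVR8-dependent genes (real 1515, highest other 2577). The 7 other splits that keep the UV-B libraries of each genotype whole still hold the difference under UV-B, and the rest, which mix them, gave at most 18 and 15 genes. With the 12 libraries regrouped at random into 4 groups of 3, a scheme taken up because such ties were foreseen, 1 of 100 splits, the real one, gave as many genes (highest other 286 and 3). In 0 of the 99 regroupings did each group hold 1 light condition, so the UV-B effect widened the spread within groups.

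The list tests of this difference stood out as well. Of 19 lists 12 were called with the preset correlation and 3 with an estimated correlation. The difference was positive for the UV-B pathway (adjusted p = 1.212e-51), flavonoid (3.199e-42) and phenylpropanoid lists (5.018e-19), which held with an estimated correlation. It was positive for the B-box (1.159e-05) and clock lists (0.0005092) and negative for the PIF target list (0.0001917), and these gave adjusted p = 0.14, 0.082 and 0.48 with an estimated correlation. The PIF target list had a median log2 fold change of -1.31 in wild type and -0.52 in uvr8-6. The DNA damage list had 0.01179 (adjusted p = 0.247 with an estimated correlation). The cell wall, PIF family, salicylic acid, root and seed lists had 0.02619, 0.04631, 0.04558, 0.03424 and 0.03424, and adjusted p = 0.48, 0.28, 0.25, 0.48 and 0.47 with an estimated correlation. Their calls rested on single libraries. The cell wall call ended without wild-type white-light replicate 1 (0.0765), wild-type UV-B replicate 1 (0.0737) or 3 (0.0618), uvr8-6 white-light replicate 2 (0.147) or uvr8-6 UV-B replicate 2 (0.0692). The PIF family call ended without wild-type white-light replicate 1 (0.0631) or 2 (0.123), wild-type UV-B replicate 1 (0.0876) or 2 (0.0578), uvr8-6 white-light replicate 1 (0.0765) or 3 (0.104), or uvr8-6 UV-B replicate 1 (0.0639) or 3 (0.0548). The salicylic acid call ended without wild-type white-light replicate 1 (0.0631) or 3 (0.0949), wild-type UV-B replicate 2 (0.0501) or 3 (0.0618), uvr8-6 white-light replicate 2 (0.0978) or 3 (0.0501), or uvr8-6 UV-B replicate 1 (0.0584) or 2 (0.0692). The root call ended without wild-type white-light replicate 2 (0.14), wild-type UV-B replicate 2 (0.0701) or 3 (0.0566), or uvr8-6 white-light replicate 1 (0.079) or 3 (0.0716), and the seed call without wild-type white-light replicate 1 (0.0765) or uvr8-6 UV-B replicate 2 (0.0975). With upper quartile scaling all 5 of these calls ended (0.0547, 0.0547, 0.0776, 0.0686 and 0.0962), and with the replicate block the PIF family (0.112) and salicylic acid calls ended (0.0626). With 1 surrogate variable the PIF family (0.0555) and root calls ended (0.0611), and without both wild-type libraries that lack QQS reads the PIF family call (0.191). Other lists gained a call. The auxin list, at 0.0994 and negative, was called without wild-type white-light replicate 2 (0.00218), wild-type UV-B replicate 2 (0.00836), uvr8-6 white-light replicate 1 (0.0241) or 3 (0.0405) or uvr8-6 UV-B replicate 3 (0.0475), without both wild-type libraries that lack QQS reads (0.0191) and with 1 surrogate variable (0.000165). The photosynthesis list was called without uvr8-6 UV-B replicate 1 (0.023) and the cell cycle list without uvr8-6 UV-B replicate 2 (0.0104). These gained calls are at the preset correlation. With all libraries and an estimated correlation camera gave the auxin, photosynthesis and cell cycle lists adjusted p = 0.79, 0.79 and 0.72.

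The DNA damage list rose under UV-B in uvr8-6. With the preset correlation the highest adjusted p without any 1 of the 6 libraries was 1.36e-07, and with 1 surrogate variable it was 1.66e-09. With an estimated correlation the adjusted p was 0.0219, and the call ended without white-light replicate 2 (0.0698) or UV-B replicate 2 (0.0572) and with 1 surrogate variable (0.0661). The median log2 fold change was 0.49 (SD 0.47 over 18 genes) before, and 0.47 (SD 0.47), 0.66 (SD 0.47) and 0.44 (SD 0.48) in these settings. It was lowest, at 0.29 (SD 0.49), without UV-B replicate 3, where the call held with an estimated correlation (0.0287). The SD is the scatter among the genes and not the error of the median, so it does not bound these moves. The settings also leave fewer degrees of freedom. The fry test of the list itself gave adjusted p = 0.00128 in uvr8-6, and 0.00218 with the replicate block. It was not run with libraries left out or with the surrogate variable. Thus 1 library and the axis that splits libraries within groups stay open as the source of the rise, since the camera calls depend on the correlation taken. Whether the genotypes differ in this response stays open. For the difference camera gave adjusted p = 0.0118 with the preset and 0.247 with an estimated correlation, and fry gave 0.0365.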

How the results depend on the processing

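Most alternatives were fixed before the values were seen; the surrogate variable, the left-out pair of wild-type libraries, the genes of the normalized table, the white-light libraries alone, the list tests with libraries left out and the estimated correlation joined with these for the DNA damage list were added afterwards. The 13 counts stayed within 1.5 times under RLE and upper quartile scaling, both filters, removal of organelle genes, limma-voom and the genes of the normalized table. The cause was not tested for the values below, except that fewer libraries leave fewer degrees of freedom. With DESeq2 the uvr8-6 response had 629 genes, uvr8-6 against wild type 6, pif4-101 pif5-1 1772, the overlap with UVR8-dependent genes 130 that fell, 118 that rose and 248 in all, and the overlap under UV-B without shared libraries 293 that rose. With the replicate block the uvr8-6 response had 367 genes, and of 114 list tests by fry 36 were called without and 34 with the block. Libraries of equal number in pif4-101 pif5-1 and wild type correlated by 0.08, 0.19 and 0.17, a hint of pairing only, and the white-light libraries alone with the block gave 1429 genes. The libraries compared alone gave 278 genes for pif4-101 pif5-1. Without both wild-type libraries that lack QQS reads uvr8-6 against wild type had 6 genes, the overlap that rose without shared libraries 81, and in uvr8-6 against wild type the PIF target and auxin lists turned direction (adjusted p = 0.00257 and 0.0144). They turned without wild-type white-light replicate 2 (0.00214 and 0.015), and over single left-out libraries both ran from 6.9e-08 to 0.645. The fits in which they turned had no replicate block and kept uvr8-6 white-light replicate 2. That library deviated together with wild-type white-light replicate 2 (correlation 0.60). With 1 surrogate variable the counts were 386 for the uvr8-6 response, 2156 for the difference, 1842 for pif4-101 pif5-1, 2061 UVR8-dependent genes, overlaps of 191, 159 and 350, and 435 and 348 without shared libraries. The variable was estimated from the same counts with the groups given and then taken as known. That can understate the error, so these higher counts do not by themselves show recovered signal. Of 114 list tests 55 were called, and 10 with an estimated correlation. Over single left-out libraries list tests gained the call in 44 cases and lost it in 46.

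Over single left-out libraries the wild-type response ran from 4218 to 5223 genes, the uvr8-6 response from 43 to 393, the difference from 877 to 1247, pif4-101 pif5-1 from 335 to 1459, wild type against uvr8-6 under UV-B from 3349 to 4103, UVR8-dependent genes from 855 to 1211, and called lists from 51 to 61. The overlap ran from 32 to 124 that fell, 7 to 97 that rose and 39 to 183 in all, and without shared libraries from 110 to 281, 26 to 238 and 281 to 517. Of 192 gene values, 23 lost their call with the compared libraries alone, 11 without the pair, 10 with limma-voom and 1 each with upper quartile scaling, the replicate block and no low-count filter. Over single left-out libraries 160 of their tests lost the call and 1230 kept their side. None turned direction. Of simulated 1.5-fold changes 34% were called in the wild-type response and 8% in the difference. These simulated comparisons called 162 and 121 genes, against 5700 and 1375 in the data, so the adjusted threshold was stricter there. The share of small changes missed in the data was therefore not measured.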

Other observations

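The tests of suberin genes, of the pair of wild-type libraries and of MRD1 and HEI10 were chosen after the result was seen, whereas the splits and the copper test were written before. Of 12 suberin genes, which make the lipid barrier of root cell walls, 6 rose and 1 fell under UV-B in wild type, with a median log2 fold change of 1.2, and 5 rose in uvr8-6, with a median of 1.26. GPAT5 had 2.23 ± 0.34 and 2.07 ± 0.34 (SE) and KCS2 1.56 ± 0.23 and 1.35 ± 0.23 in wild type and uvr8-6, whereas FAR1 fell in wild type (-2.49 ± 0.65). With an estimated correlation the 12 genes gave adjusted p = 0.198 in wild type and 0.00654 in uvr8-6. The list was drawn up after 4 members had been seen, so the other 8, of which 3 rose in wild type and 2 in uvr8-6, were tested, with p = 2.15e-10 by camera in uvr8-6 (adjusted p = 0.0363 with an estimated correlation) and p = 0.00391 in wild type (adjusted p = 0.30 with an estimated correlation). A response that needs no UVR8 is a candidate explanation, and the difference between the genotypes was not called by camera on the edgeR fit (adjusted p = 0.988), which does not show that they are equal. Without UV-B replicate 2 of uvr8-6 the camera test of the 8 genes in uvr8-6 gave p = 7.56e-07 at the preset correlation. Their median log2 fold change was then 0.81, against 1.13 with all libraries. An estimated correlation was not taken in that setting.

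Wild-type white-light replicate 2 and wild-type UV-B replicate 1 were nearly without reads of QQS, an orphan gene of starch metabolism, with 4 and 6 reads against 325 to 695 in the other wild-type libraries. All 9 mutant libraries were low as well, with 5 to 32 QQS reads. Depth is argued against by a ratio of 65.4 between the lowest of the others and the highest of the pair in CPM, and a mutant under a wild-type label by a UVR8 level of at least 81.45 CPM in the pair, against at most 19 in uvr8-6, and by PIF5 levels of 77.1 and 106.5 CPM, against at most 5.46 in pif4-101 pif5-1. Beside QQS and AT3G01345, 2 genes, FRO5 and AT5G07570, parted the pair from the other wild-type libraries by 8-fold, against 0 for any other such pair, 5 against 1 at 4-fold and 29 against 8 at 2-fold, but 2, 3 and 13 of these genes parted uvr8-6 white-light replicate 2 and UV-B replicates 1 and 3 from the other uvr8-6 libraries alike. A separate seed stock or growth batch therefore stays open (2 genes at 8-fold, both on the axis of FRO5), and no biological explanation was tested.

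MRD1 and HEI10, lower in uvr8-6 in white light, are 1 place apart in the order of loci, and 0 of 9 tested neighbours were lower there. Under UV-B AT1G53430 was lower in uvr8-6 (wild type higher by 0.49 on the log2 scale, adjusted p = 0.000554) and MUM4 higher (wild type -0.27, adjusted p = 0.0221). Since 4903 of 20833 genes were called in that comparison, these calls do not by themselves mark the locus. Activation of UVR8 by UV-B is argued against, since MRD1 had a log2 fold change of -0.13 under UV-B in wild type. A lesion or a stretch of another background at this locus in the uvr8-6 line is a candidate explanation. Reads shared between both genes could contribute and cannot be told apart, since the ratio of HEI10 to MRD1 reads was 26.4 times higher in uvr8-6, which leaves it open.

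In 5 libraries of 4 groups (wild-type white-light replicate 2, wild-type UV-B replicate 1, uvr8-6 white-light replicate 2 and uvr8-6 UV-B replicates 1 and 3) the reductase gene FRO5 stood at 20.8 CPM or more, and in the other 10 at 1.2 or less. Between these libraries and the others of their groups 1817 genes differed, 883 higher and 934 lower, although these groups were defined from the data. A lower copper supply of these plates was predicted to raise 5 unseen genes by a median above 1 on the log2 scale and to lower 3 by below -1. The medians were 0.55 (SD 0.60) and -0.52 (SD 0.06), so the prediction missed its size, while 7 of 8 genes were called in the predicted direction and ZIP2 was not (-0.38). Both medians also met the condition written before as counting against this explanation. The spread of the rising genes was not part of that condition. A weaker form of the explanation was not predicted and stays open. The 7 of 8 calls in the predicted direction carry little weight for it, since that count was not part of the written condition. FRO5, by which the libraries were chosen, was also listed among the genes that rise without copper.

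For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The wild-type response had 5348 genes with the real split, as the 1 largest, and 0 at the highest other, uvr8-6 against wild type 3 and 1, pif4-101 pif5-1 278 and 0, and wild type against uvr8-6 under UV-B 4936 and 2. In the uvr8-6 response 2 of 10 splits gave as many genes, with 167 for the real split and 568 for white-light replicates 1 and 3 with UV-B replicate 2 against the rest. That split follows the FRO5 libraries and points to a structure of the samples, and with 1 surrogate variable the response had 386 genes.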
